A study of Mus musculus with 2 samples.

How the data were processed

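RNA-seq was performed on round spermatids of C57BL/6 mice, with 1 library from wild-type mice and 1 labelled Epc-dKO from mice deficient for Epc1 and Epc2. Per the labels' protocols, directional libraries were made from total RNA with the NEBNext Ultra Directional kit, amplified by PCR, and sequenced on an Illumina HiSeq instrument. The values used are FPKM per gene as deposited by the authors, in 1 table with 1 column per library. Per the submitters' processing notes, Cufflinks 2.2.1 and the mm9 genome were used. The aligner, the annotation, the strand setting and any scaling between the libraries are not given in the sources used here. FPKM is divided by transcript length and by the mapped total, so a few abundant transcripts can shift all other values, and short transcripts rest on fewer fragments at a given FPKM. The values hold no counts, and the read depth is unknown; no interval or detection limit that needs it was computed, and a value of 0 is reported only as listed at 0. PCR duplicates could not be assessed from these values.

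The table had 23235 rows. A single row held library codes and no gene, and was left out; 23234 genes with 0 duplicated symbols remained. The 2 libraries were grouped by their genotype labels. With 1 library per group no test between genotypes is possible, no p-value was computed, and no correction for multiple testing applies. For each gene the log2 ratio was log2((FPKM + 1) in the library labelled Epc-dKO over (FPKM + 1) in the wild-type library). Genes with a mean FPKM of 1 or more over both libraries were called expressed, and a gene was counted as higher or lower when it differed by at least 2-fold on this scale. Before the data were examined, 24 gene lists were fixed from textbook knowledge of spermatids, other testis cells and general cell functions, holding 707 entries, of which 703 matched a symbol. For each of the 22 lists with 5 or more expressed members, the median log2 ratio was ranked among the medians of 10000 random lists of the same size matched on mean FPKM (20 bins of rank). The list of endothelial, blood and immune markers had 1 expressed member and is given by value. The list of mitochondrial genome transcripts was left without members, and those transcripts were not analysed here. Bootstrap intervals (95%, 2000 samples over genes) describe the spread between genes, not between animals.

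The rule for named genes was also fixed in advance. It takes Epc1 and Epc2; among genes with a mean FPKM of 5 or more, the 12 with the largest rise and the 12 with the largest fall, leaving out predicted, uncharacterised and small RNA symbols; in each list the 2 most abundant and the 2 most changed members; and the 5 highest genes of each library. Of these the text gives those that describe each group. Genes named outside the rule are said to have been chosen after their values were seen.

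Transcript lengths and chromosomes were looked up by symbol in GENCODE M21, which annotates GRCm38 and not mm9, so no coordinate is printed; 98.7% of expressed genes had an entry. The alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no minimum FPKM, a minimum mean FPKM of 5, rescaling of each library to the fixed sum of the TPM scale, to a median ratio of 1, to its upper quartile or to its sum without the 100 highest genes, a 4-fold rule, matching on wild-type FPKM alone, leaving out the most changed member of a list, and keeping the highest row of a duplicated symbol. Further alternatives, chosen after seeing the data, matched random lists on transcript length as well and left out small RNA genes. The ranking and the 2-fold rule were tested on simulated data for this comparison with 23234 genes. With a noise SD of 0.3 on the log2 scale, 98.5% of 200 genes changed 4-fold were recovered, 0.0193% of unchanged genes were counted, 7.0% of 200 unchanged lists of 20 genes fell outside the central 95%, and 100% of lists shifted by 0.5 did. This noise was drawn independently for each gene and was the same at every expression level and transcript length. In the data the share of expressed genes past 2-fold was 8.84% at 800 nt or less and 2.52% above 3000 nt. The simulated 0.0193% and 7.0% are therefore not error rates for the counts and lists below. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.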

Results

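RNA-seq was collected from mouse round spermatids, the haploid germ cells that follow meiosis and precede elongation of the sperm head. The animals were of the C57BL/6 strain, and the comparison asked how gene expression in these cells differs between wild-type mice and mice deficient for both Epc1 and Epc2. These genes encode subunits of the NuA4/TIP60 histone acetyltransferase complex. Each genotype was represented by 1 library, and the second is called here the library labelled Epc-dKO. FPKM values (fragment counts scaled to transcript length and to the mapped total of the library) were given for 23234 genes and summed to 193611 in the wild-type library and 198081 in the library labelled Epc-dKO. The read depth behind them is unknown, so no counting interval or detection limit is given. With 1 library per genotype no difference has a replicate check and no p-value is given. A gene is said to have risen or fallen only when it passed a fixed 2-fold rule on log2((FPKM + 1)/(FPKM + 1)), a scale that understates the change of low genes.

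Epc1 and Epc2 themselves were not lower in the library labelled Epc-dKO. Epc1 had an FPKM of 11.4 in the wild-type library and 13.6 in the library labelled Epc-dKO, a log2 ratio of 0.24. Epc2 had 7.12 and 10.5, a log2 ratio of 0.51. Both lay within 2-fold. A gene-level FPKM includes exons outside any deleted part, so these values neither bear out nor exclude the genotype label, and every direction below is that of the library labelled Epc-dKO against the wild-type library.

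Most of the transcriptome lay close to the diagonal. Of 10438 genes with a mean FPKM of 1 or more, 287 (2.75%) were at least 2-fold higher in the library labelled Epc-dKO, 196 (1.88%) were at least 2-fold lower, and 9955 (95.4%) lay within 2-fold. The median log2 ratio was -0.05, with quartiles of -0.34 and 0.24. Across genes, which are not independent replicates, Pearson's r of the log2 values was 0.914 and Spearman's rank coefficient was 0.897. The genes with the highest FPKM were largely shared. Mir5109, Pabpc1, which encodes a poly(A)-binding protein, the flippase gene Atp8b3 and Odf2, an outer dense fibre gene of the sperm tail, were among the 5 highest genes of both libraries. Mir5109 is a microRNA symbol without an entry in the annotation used for lengths, so its rank is uncertain. Odf2 had an FPKM of 904 in the wild-type library and 1014 in the library labelled Epc-dKO. Small RNA genes made up 57 of the higher and 58 of the lower genes, and without them the counts were 230 and 138, an alternative chosen after seeing the data. Higher genes made up 59.4% of the genes past the 2-fold rule, but this split depended on the scale: it was 34.1% (545 higher, 1054 lower) on the TPM scale, with both libraries rescaled to the same larger sum, 39.9% (433 higher, 652 lower) with a pseudocount of 0.1 and 48.7% with a pseudocount of 0.5.

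**Figure D1:**
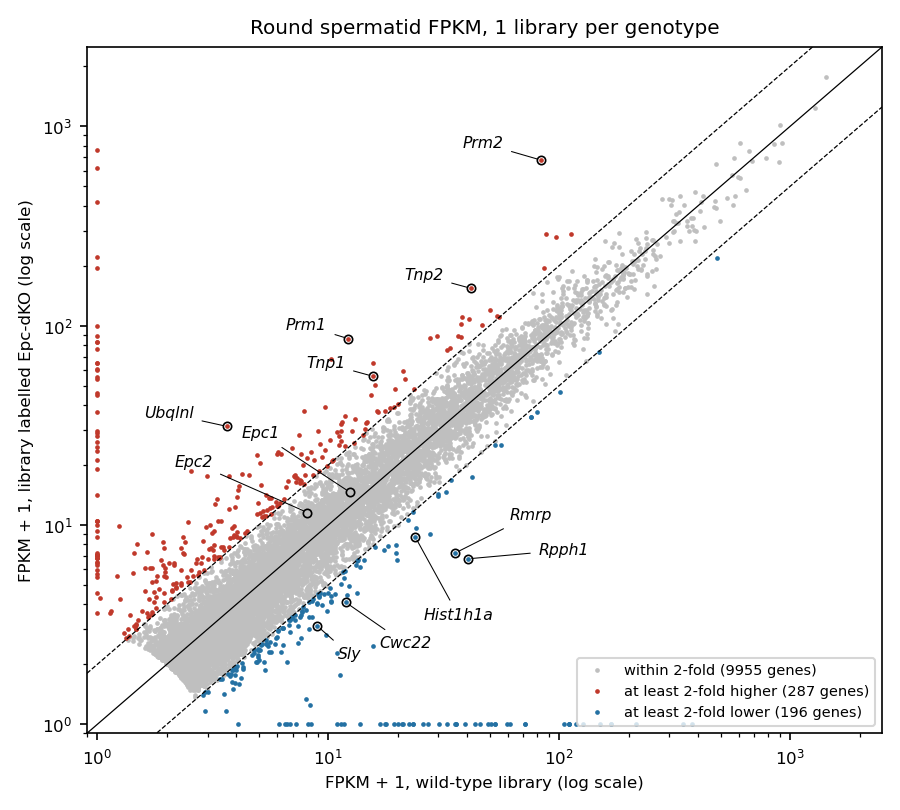
FPKM + 1 of each gene with a mean FPKM of 1 or more in the wild-type library (x axis, log scale) and in the library labelled Epc-dKO (y axis, log scale), 1 library each. Points are genes, the solid line marks equal values, the dashed lines mark 2-fold differences, and circled genes are named in the text; 287 genes lie on or above the upper dashed line, 196 on or below the lower one, and Epc1 and Epc2 lie between them.

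Genes of transition proteins, protamines and linker-like spermatid proteins had the highest median of the 22 gene lists ranked, and 4 of the 7 rose. Prm2, which encodes protamine 2, rose from an FPKM of 82.8 to 675 (log2 ratio 3.01), and Prm1, for protamine 1, rose from 11.2 to 85.0 (2.82). The transition protein gene Tnp2 rose from 40.5 to 153 (1.89). Tnp1, named after its values were seen, rose from 14.6 to 54.8 (1.84). The other members of the list of 7, also named after their values were seen, did not pass the rule. The linker histone-like genes H1fnt and Hils1 had log2 ratios of 0.71 and -0.52, and Prm3 had -0.45. The median of the list was 1.84, above all 10000 random lists of the same size matched on mean FPKM, and its lowest percentile over the alternatives tried was 99.9. The 7 genes are short, with a median longest transcript of 554 nt.

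Other genes with the largest rises under the naming rule, which leaves out small RNA, predicted and uncharacterised genes, were of several kinds. Ubqlnl, a ubiquilin-like gene, rose from an FPKM of 2.65 to 30.2 (log2 ratio 3.09). Spatc1, which encodes the centrosomal protein speriolin, rose by a log2 ratio of 2.56, and Fscn3, a testis fascin gene, by 2.25. Spert, a spermatid-associated gene, rose from 14.6 to 63.9 (2.06), and Tppp2, a tubulin polymerization-promoting protein gene, rose from 1.46 to 9.33 (2.07). The near-identical ketone body enzyme genes Oxct2a and Oxct2b rose from 4.08 to 19.5 and from 3.90 to 21.5, and Fam75d3, of a multigene family, rose from 2.29 to 12.5. These paralogs can share reads, and their separate values are uncertain. Vav2 rose from 6.82 to 36.3 (2.25) and Cntfr, for the ciliary neurotrophic factor receptor, from 3.24 to 17.1 (2.09).

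Genes of the sperm tail and fibrous sheath, not all of them structural, were shifted slightly upward as a list. The list of tail and fibrous sheath genes had 47 expressed members, of which 4 rose and 0 fell, with a median log2 ratio of 0.17 at the percentile of 97.8 among matched random lists. Spata18 rose from an FPKM of 36.7 to 101 (log2 ratio 1.44), Txndc2 from 32.6 to 76.6 (1.21), and Akap4, the main scaffold gene of the fibrous sheath, from 85.0 to 193 (1.17). The fourth, Spata3 (1.16), was named after its values were seen. Other spermiogenesis lists stayed inside the central 95% of random lists. Head shape, manchette and cytoplasm removal genes had 3 of 35 members that rose, among them Spem1 (log2 ratio 1.72) and 4933402P03Rik (1.56), the third, Tssk6 (1.08), being named after its values were seen; their median was 0.07, at the percentile of 66.7. Sperm glycolysis and energy genes had 1 of 24 that rose, the soluble adenylyl cyclase gene Adcy10 (1.49), and a median of 0.14, at 87.8. In that list Gapdhs had an FPKM of 112 in the wild-type library and 187 in the library labelled Epc-dKO, and Ldhc had 466 and 391. Acrosome genes had 1 of 40 that rose, Fam71b (1.80), and a median of 0.02, at 49.7. None of the 31 transcription and RNA regulators of spermiogenesis passed the rule; their median was -0.00, at 41.5, with Taf7l at -0.95 and Nsun7 at 0.73. None of the 22 genes of the piRNA pathway and chromatoid body did either (median -0.06, at 25.1).

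Chromatin genes upstream of histone replacement showed no member past 2-fold in 3 lists. The 16 NuA4/TIP60 subunit genes other than Epc1 and Epc2 had a median of -0.13, at the percentile of 9.88. Their most abundant members were Morf4l1, with an FPKM of 423 in the wild-type library and 313 in the library labelled Epc-dKO, and Ep400, with 123 and 105. The 22 other histone acetyltransferase and deacetylase genes had a median of -0.10, at 23.4. The 19 regulators of histone replacement had a median of -0.17, at 3.14; this percentile was 1.49 when random lists were also matched on transcript length, an alternative chosen after seeing the data.

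Histone genes were lower. Of 26 replication-dependent histone genes, 7 fell and 0 rose, and the median log2 ratio of -0.70 lay below all 10000 random lists. Hist1h1a fell from an FPKM of 22.8 to 7.74 (log2 ratio -1.44) and Hist1h4c from 5.37 to 1.49 (-1.36). Testis and replacement histone variants had a median of -0.42 over 13 genes, at the percentile of 0.42, and went both ways. The testis H2B gene Hist1h2ba fell from 31.2 to 13.7 (-1.13) and Hist1h2aa, its H2A partner, named after its values were seen, fell from 28.9 to 12.9 (-1.10). In contrast, H2afb1 rose from 0.924 to 5.30 (1.71). The testis linker histone gene Hist1h1t, also chosen after its values were seen, had 5.64 and 5.59. Histone genes are multicopy and can share reads, so single members are uncertain. Genes of the cytosolic ribosome were also lower: 65 of 74 had a log2 ratio below 0, 2 fell and 0 rose, and the median of -0.41 lay below all random lists. Rplp0 had 150 in the wild-type library and 109 in the library labelled Epc-dKO, and Rpl41 had 143 and 118. Rps19 (-1.24) and Rpl10 (-1.02) passed the rule from FPKM values of 3.87 and 4.38. Ribosomal protein genes have many pseudogenes that can share their reads. The histone and ribosomal lists moved in the same direction as the spermatogonial list given below.

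The list of sex chromosome genes of spermatids was lower. Its members, among them Eif2s3y, Ddx3y, Uty and Kdm5d, were not checked for transcription in other testis cells. The median over 17 genes was -0.55, at the percentile of 0.01, with 4 genes that fell and 1, Akap4, that rose. Sly, a multicopy Y-linked regulator of sex chromosome expression in spermatids, fell from an FPKM of 7.94 to 2.12 (log2 ratio -1.52). The other falls, named after their values were seen, were the multicopy Y-linked genes Ssty1 (-1.10) and Ssty2 (-1.07) and the gene Ube2dnl (-1.05). Reads of such multicopy genes cannot be assigned to one copy with certainty. With a minimum mean FPKM of 5 the list stood at the percentile of 7.12, inside the central 95%. The list moved in the same direction as the spermatogonial list given below (median -0.73) and as all 320 expressed X-linked genes, whose median was -0.47 in a grouping chosen after the values were seen.

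Under the naming rule, the largest falls were in short noncoding RNAs. The rule leaves out microRNA, small nucleolar and similar small RNA symbols, among which 12 genes went from above 100 FPKM in the wild-type library to a listed 0 and 5 from a listed 0 to above 100 FPKM. Rpph1, the RNA of RNase P, fell from an FPKM of 39.2 to 5.76 (log2 ratio -2.57), and its relative Rprl3 fell from 14.6 to 1.47 (-2.66). Rmrp, the RNA of RNase MRP, fell from 34.4 to 6.23 (-2.29). Their longest annotated transcripts are 281 to 319 nt. Among coding genes, the splicing factor gene Cwc22 fell from 10.9 to 3.09 (-1.54) and Gaa, for lysosomal acid alpha-glucosidase, fell by 1.44 on the log2 scale to 3.43. The ribosome assembly GTPase gene Eftud1 fell from 18.6 to 6.25 (-1.43). Myh6, a cardiac myosin heavy chain gene, fell by 1.41 on the log2 scale. Esx1, an X-linked homeobox gene, and Fam46b each fell by 1.32.

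Markers of spermatogonia, the mitotic germ cells at the base of the tubule, were lower in the library labelled Epc-dKO. The 17 expressed markers, of 30 listed, had a median log2 ratio of -0.73, below all random lists, and 16 of the 17 lay below 0. Dmrt1 fell from an FPKM of 7.49 to 2.47 (log2 ratio -1.29) and Crabp1 from 3.77 to 1.27 (-1.07). Dazl, the most abundant with Dmrt1, had 7.42 and 3.44 (-0.92). The 6 expressed Sertoli cell markers, of 28 listed, had a median of -0.57 at the percentile of 1.58, with no member past 2-fold and Clu at 8.29 and 5.03. This rank did not hold without the minimum FPKM (median -0.03, percentile 68.0), on the TPM scale (3.85) or without its most changed member (4.11). Peritubular and stromal markers (9 of 18 expressed) had a median of -0.58 at 0.21, though Actg2, a smooth muscle actin gene, rose from 15.3 to 36.2 (1.19). Leydig cell markers (12 of 18 expressed) had a median of -0.27 at 15.0. Ptgds, which encodes a prostaglandin D synthase, fell from 9.29 to 3.09 (-1.33), Agt, for angiotensinogen, fell by 1.13 and Insl3, for a Leydig cell hormone, by 1.03, while the steroidogenic gene Cyp17a1 had 7.78 and 8.79. Of 29 endothelial, blood and immune markers 1 was expressed, Vwf, with a log2 ratio of -0.12.

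Stress and immediate early genes were lower as a list, the same direction as the spermatogonial markers. Of 18 expressed members 5 fell and 0 rose, and the median of -0.50 lay below all random lists. Fos fell from an FPKM of 4.67 to 1.31 (log2 ratio -1.30) and Egr1 from 10.4 to 4.06 (-1.17). The abundant chaperone gene Dnajb1 had 97.0 and 79.2. Markers of pachytene and earlier spermatocytes, the meiotic cells that precede spermatids, had a median of -0.01 over 35 genes, at the percentile of 66.6. Of these, 2 fell, Zcwpw1 (-1.15) and Tex101 (from an FPKM of 12.4 to 5.69), and the abundant Mns1 had a log2 ratio of 0.35. p53 targets and apoptosis genes had 0 of 14 members past 2-fold and a median of -0.01, at 73.7, but -0.30 at 26.7 on the TPM scale and -0.08 at 31.2 without a minimum FPKM, all inside the central 95%. The DNA double-strand break response had 0 of 33 and a median of -0.14, at 20.96. Of the 22 lists with 5 or more expressed members, 2 lay above and 8 below the central 95% of their random lists. The 1.1 expected outside holds only if lists are independent draws and the genes within a list vary independently. Ranked among 1000 random lists, 12 of the 19 autosomes also lay outside the central 95%, in a grouping chosen after the values were seen. A list outside its range is therefore not by itself beyond chance. The gene lists share some genes and their ranks describe these libraries only.

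**Figure D2:**
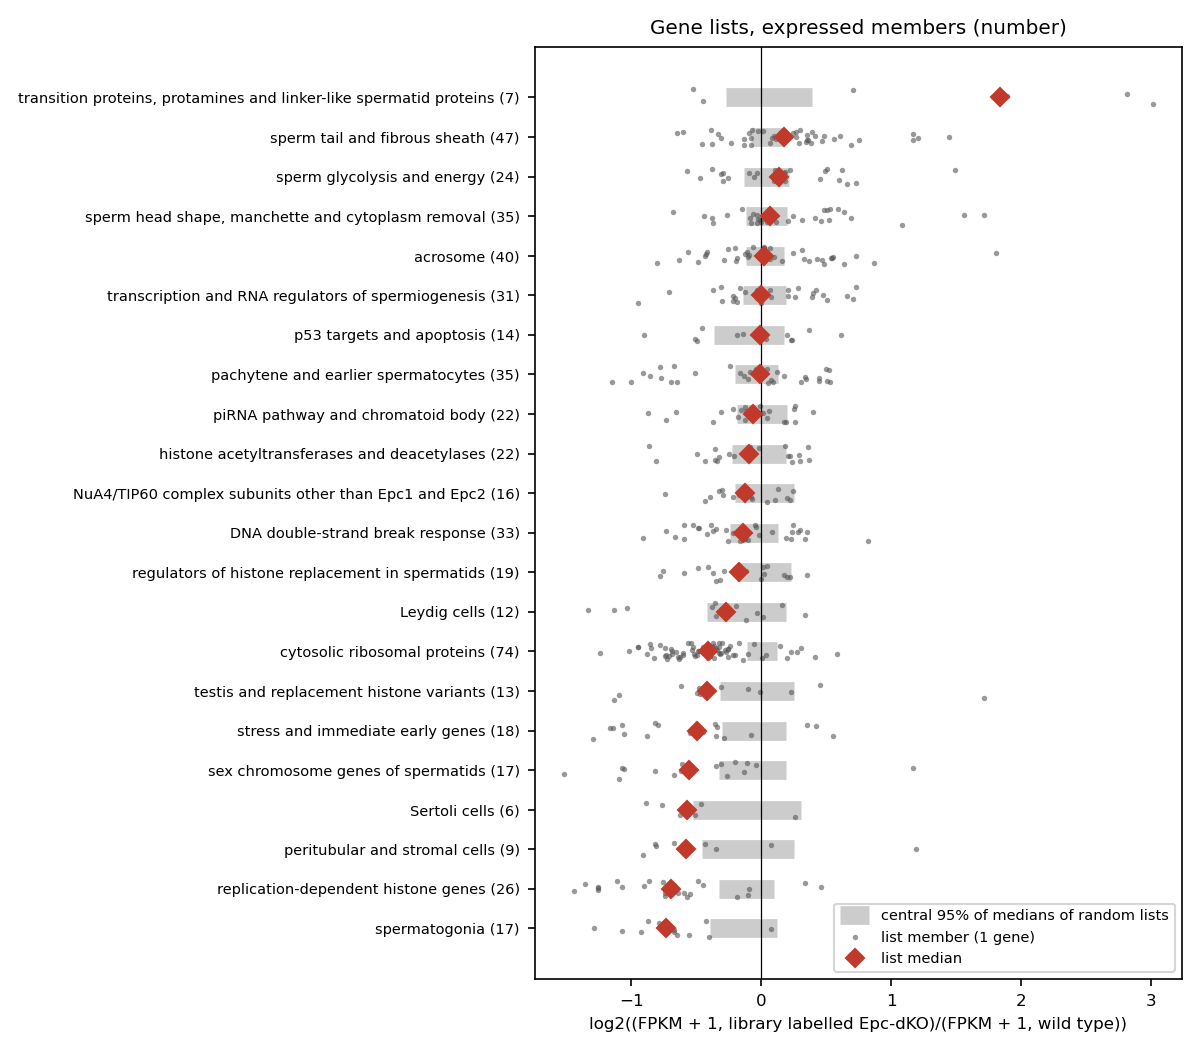
Log2 ratio of FPKM + 1, library labelled Epc-dKO over wild-type library, for the expressed members (small points) of 22 gene lists, with the number of members in brackets, 1 library per genotype. Diamonds are list medians and grey bars hold the central 95% of medians of 10000 random lists matched on mean FPKM; the protamine and transition protein list stands at 1.84 and the spermatogonial list at -0.73.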

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

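Under the alternatives tried, no list outside the central 95% of random lists and no named gene past the 2-fold rule reversed its direction. For named genes this outcome was all but fixed. A pseudocount cannot change the sign of a ratio, and the rescalings shifted the libraries against each other only slightly. The protamine and transition protein list kept a median of 1.27 to 1.90, and the spermatogonial, ribosomal and replication-dependent histone lists stayed below all random lists wherever they gave a value. With a mean FPKM of 5 or more, 6 lists had too few members to give one: spermatogonia, Sertoli, Leydig, peritubular, replication-dependent histones and p53 targets. The rescalings moved the median of all genes by at most 0.1. The counts of higher and lower genes moved most: 433 and 652 with a pseudocount of 0.1, 364 lower with 0.5, 166 and 105 with a mean FPKM of 5 or more (fewer genes are counted), 545 and 1054 on the TPM scale, where 15151 genes pass the minimum and the pseudocount weighs less, and 76 and 59 under the 4-fold rule. List medians of testis histone variants, replication-dependent histones and spermatogonia became -0.53, -0.997 and -1.11 with a pseudocount of 0.1 and -0.56, -0.97 and -1.02 on the TPM scale. With a pseudocount of 0.5 the variants stood at -0.51 and spermatogonia at -0.89. Without a minimum, which adds genes near 0, replication-dependent histones stood at -0.56, spermatogonia at -0.53 and Sertoli markers at -0.0302, at the percentile of 68.0. Sertoli markers also moved inside the central 95% on the TPM scale (3.85) and without their most changed member (4.11). With a mean FPKM of 5 or more the sex chromosome list stood at 7.12 and the double-strand break list had a median of -0.0154. With random lists matched on length as well, chosen after seeing the data, the histone replacement regulators stood at 1.49; the cause was not tested for these last shifts. The 2-fold side of named genes was kept in 620 of 654 comparisons. Keeping the highest row of duplicated symbols could not change a value, since 0 symbols were duplicated. No paired analysis was possible because each genotype has 1 library. The unknown depth limits statements on low genes.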

Other observations

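The grouping by chromosome, the tests of late spermatids, of an even background and of fewer spermatogonia and somatic cells as a source of the lower markers, and the test of X-linked genes against length and level were chosen only after the results were seen. So was the requirement that a list's bootstrap interval clear the random range before a percentile counts for or against an explanation, and so was the value of X-linked genes without small RNA genes. All directions assume that the library labelled Epc-dKO is what its label says, and Epc1 and Epc2 were not lower in it.

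Genes on the X chromosome were lower in the library labelled Epc-dKO as a class. The median log2 ratio of 320 expressed X-linked genes was -0.47 (95% bootstrap interval over genes -0.50 to -0.43), and 265 of them lay below 0, while the medians of the 19 autosomes ran from -0.09 to 0.06. On the Y chromosome, 9 expressed genes had a median of -0.35 (bootstrap interval -1.07 to -0.13), at the percentile of 6.95 among 1000 random lists, inside their central 95%. By the same ranking 12 of the 19 autosomes lay outside the central 95% of theirs, so it does not single out the X chromosome. The X-linked shift was not carried by the lists described above, since 296 X-linked genes in none of the lists had a median of -0.46. Among abundant X-linked genes, Uba1, which encodes the ubiquitin-activating enzyme, had an FPKM of 57.3 in the wild-type library and 38.5 in the library labelled Epc-dKO, Huwe1 had 27.4 and 20.3, and Akap4 went the other way with 85.0 and 193; these genes were picked after their values were seen. Under the pseudocounts and rescalings tried, the X-linked median ran from -0.67 to -0.44 and the autosomal median from -0.07 to -0.00.

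Expression level and transcript length do not account for the lower X-linked genes: their median lay below all 10000 random lists matched on both (percentile 0), whose central 95% ran from -0.16 to -0.04. Fewer spermatogonia and somatic cells, which transcribe the X chromosome more fully than spermatids do, stay open. The 10 X-linked genes with a mean FPKM of 20 or more, a level above the 5.43 of the highest spermatogonial marker, had a median of -0.33 at the percentile of 0.3. This percentile met the bound set beforehand against that explanation, but the bootstrap interval of the median (-0.56 to 0.52) overlaps the central range of random lists (-0.21 to 0.33); without 3 small RNA genes, 6 of 7 lay below 0, with a median of -0.41 at the percentile of 0.3, and the interval (-0.56 to -0.13) still overlaps that of random lists (-0.27 to 0.40), so the test does not decide. A genotype effect on the X chromosome after meiosis also stays open, as untested with 1 library per genotype.

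The higher protamine and transition protein genes were not part of a rise of short transcripts as a class: 289 expressed coding genes of 800 nt or less outside the list had a median of -0.19 (bootstrap interval -0.24 to -0.09). Unstable estimates of short transcripts stay open: the list median lay at the percentile of 99.9 among random lists matched on length and FPKM, past the bound set beforehand against that explanation, but 3 of the 7 members did not pass 2-fold and the bootstrap interval of the median (-0.45 to 2.82) overlaps the random range (-0.55 to 0.51). A larger share of late spermatids in the dKO-labelled sample also stays open: the tail and fibrous sheath list stood at the percentile of 97.8 (97.8 to 99.8 over the alternatives), but these percentiles had been seen, and the bootstrap interval of its median (0.06 to 0.34) overlaps its random range (-0.08 to 0.17). The most abundant genes of that list, Odf2 and Tcp11, had FPKM values of 904 and 665 in the wild-type library and 1014 and 755 in the other. The acrosome list stood at the percentile of 49.7, and Prm3 and Hils1 had log2 ratios of -0.45 and -0.52. The stage at which these genes are transcribed was not examined here. Their values therefore count neither for nor against a larger share of late spermatids. An effect of the genotype remains untested.

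The lower spermatogonial markers, and the somatic lists, of which Leydig markers stayed inside the central 95% of random lists and Sertoli markers did so under 3 alternatives, were not matched by an even background. Over 1528 genes of families expected to be silent here (olfactory, vomeronasal and taste receptors and keratin-associated proteins), the mean wild-type minus dKO-labelled difference was -0.0285 FPKM (bootstrap interval -0.045 to -0.0158), against a median of 1.34 FPKM for the spermatogonial list. Fewer spermatogonia and somatic cells in the dKO-labelled sample may be the source, but bootstrap intervals lay below the median of all genes for 2 of the 4 lists of spermatogonial, Sertoli, Leydig and peritubular markers. The intervals of the other two reach that median, with Actg2 and Cyp17a1 not lower, and markers at these levels can also be transcribed in spermatids. The 2 libraries cannot separate cell composition from genotype.

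Of 727 small RNA genes, 5 were listed at 0 in the wild-type library and above 100 FPKM in the library labelled Epc-dKO, and 12 were the reverse. By longest transcript, the share of expressed genes past 2-fold was 8.84% at 800 nt or less and 2.52% above 3000 nt. The median log2 ratio was -0.18 at 800 nt or less and -0.03 above 3000 nt. The replication-dependent histone and ribosomal lists, with median longest transcripts of 514 and 1048 nt, lay below all random lists also matched on length.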
